A study of Mus musculus with 21 samples.

How the data were processed

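Polyadenylated RNA was sequenced from whole spleen (12 libraries) and from myeloid cells enriched from spleen (9 libraries) of 4-day-old C57BL/6 pups, labelled wild type or knockout of the IL-27 receptor alpha chain, uninfected or infected with Escherichia coli for 24 hours. Per the labels the libraries were made with a KAPA mRNA HyperPrep kit. The series also mentions chromatin accessibility, which was not analysed here. Libraries were grouped by tissue, genotype label and infection, all columns of both tables matched a sample, and none was left out.

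Per the labels the authors aligned reads with Subread to mm10 and counted them with featureCounts. Their versions, the annotation and the strand setting were not given in the sources used here. The authors deposited log2 values of RPKM + 1, with 0 written as 0.0001, and these were used as deposited after 0.0001 was set back to 0. The base of the logarithm was inferred from the values. There were 20298 entries for spleen and 21073 for myeloid cells. In each, 27 symbols that a spreadsheet had turned into dates were left out. Symbols were matched to GENCODE M21 (GRCm38) for coordinates and GC content, with 97.8% matched in each table. The spleen table held 55 genes on chromosome X and 4 on Y, against 804 and 21 in the myeloid table, so sex could not be read from it.

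Read counts were not used here. Depth was estimated from the spacing of the lowest values of each library, a method with a largest error of 0.13% on simulated data. It lay between 3.41 M and 8.49 M reads in spleen and between 3.41 M and 18.83 M in myeloid libraries. The simulation took gene lengths as nearly exact. In the real libraries RPKM times annotated length summed to 1.56 M to 1.63 M in spleen and 1.58 M to 1.66 M in myeloid cells. Matching lengths would give less, so the real error may be larger.

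Each table was fitted with limma 3.58.1 in R 4.3.3 as 1 linear model of 4 groups with moderated variances that follow a trend on mean expression. The residual degrees of freedom were 8 in spleen and 5 in myeloid cells, and the prior degrees of freedom 4.66 and 5.43. Genes with at least 1 RPKM in 3 spleen or 2 myeloid libraries were tested, 12063 and 14120 genes. There were 5 comparisons per table: infection within each genotype label, genotype label within each infection state, and the difference between the 2 infection responses. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The group with 1 myeloid library was assumed to vary like the others. All p-values of single genes are from this moderated fit unless a test is named.

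Genes were named by a rule: an adjusted p below 0.05, a mean of at least 5 RPKM in the higher group, no overlap between the libraries of the groups compared, and the 8 largest changes each way. Il27ra was always reported. Predicted genes, immunoglobulin and T cell receptor segments, histone genes and ribosomal pseudogenes were passed over. A further 41 gene lists were fixed, of which 40 had at least 5 tested members in each table. Lists were tested with camera at a correlation of 0.01, and again with an estimated correlation and with fry. Shared genes were counted with one-sided Fisher exact tests, adjusted over 10 overlaps. These tests take genes as independent and do not measure the spread between libraries. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. A few list members and the values of Clgn, Wdfy1, Efcab7, Car1 and Nnt in other comparisons were added as examples after the results were seen.

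The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, removal of haemoglobin genes with every library rescaled to the same RPKM total, a constant variance prior, a fit of only the 2 groups compared, a 2-fold minimum, the replicate number as a block, and the omission of each library in turn. Others were added after seeing the data: removal of a lowess trend on GC content per library, removal of haemoglobin genes with their share alone given back and no other rescaling, autosomal genes only, a pancreas score as covariate in spleen and a Y-linked score as covariate in myeloid cells. The labels do not say what a replicate number marks. Same-numbered uninfected and infected wild-type spleens deviated together from their group means in 3 of 3 pairs (correlations 0.535, 0.224 and 0.129), which no other pair of groups did, so a block in the wild-type spleens alone was also tried, chosen after seeing the data. The planned sex covariate was not run because Xist is in neither table.

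The fit was tested on simulated data with the same groups. These had independent genes, the same normal spread for a gene in every group, and few changed genes, so recovery in the real data may differ. With a true log2 difference of 2 it recovered 98.6% of genes for infection in wild-type spleen, 97.1% for the difference between responses in spleen, 45.7% for infection in wild-type myeloid cells and 0% for the difference between responses there. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.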

Results

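Spleen RNA was measured in 4-day-old C57BL/6 mouse pups of 2 labelled genotypes, wild type and knockout of the interleukin-27 receptor alpha chain, with or without infection by Escherichia coli O1:K1:H7 for 24 hours. IL-27 is a cytokine of the IL-12 family that signals through this receptor, and the strain is an encapsulated extraintestinal isolate used here as a model of neonatal sepsis. Polyadenylated RNA was sequenced from whole spleen, with 3 libraries in each of the 4 groups, and from myeloid cells enriched from spleen. The myeloid groups held 3 uninfected and 3 infected wild-type libraries, 1 uninfected library labelled knockout and 2 infected libraries labelled knockout. The depth estimated from the spacing of low values lay between 3.41 M and 8.49 M reads in spleen. Values are log2(RPKM + 1), so a fold change of a low gene is understated. The labels do not state that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

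The targeted gene, Il27ra (chromosome 8, 84030294 to 84042589, GRCm38), was higher, not lower, in the spleen libraries labelled knockout. In uninfected spleen it stood at 1.93, 0.673 and 1.67 RPKM in the wild-type libraries and at 4.7, 3.18 and 3.81 RPKM in the libraries labelled knockout. In infected spleen the wild-type libraries held 2.67, 1.83 and 1.57 RPKM and those labelled knockout held 3.15, 3.49 and 3.73 RPKM. The difference was 1.04 on the log2 scale in uninfected spleen (SE 0.221, adjusted p = 0.174) and 0.57 in infected spleen (SE 0.221, adjusted p = 0.0689), labelled knockout minus wild type, with all 6 libraries labelled knockout above all 6 wild-type libraries. The infected difference passed the threshold without wild-type infected replicate 1 (adjusted p = 0.0346) or without wild-type uninfected replicate 2 (adjusted p = 0.0291). It also passed in a fit of only the 2 groups compared (adjusted p = 0.0387) and with a pancreas score as covariate, chosen after seeing the data (adjusted p = 0.0486). Over 24 alternatives its adjusted p ranged from 0.0291 to 0.226. In myeloid cells Il27ra stood at 2.64, 3.14 and 2.27 RPKM in uninfected wild type, 0.78, 0.129 and 0.519 RPKM in infected wild type, 1.84 RPKM in the uninfected library labelled knockout and 2.37 and 1.72 RPKM in the infected libraries labelled knockout. The uninfected difference was -0.37 there (adjusted p = 0.548), with the 1 library labelled knockout below all 3 wild-type libraries. It was 0.11 without haemoglobin genes and with every library rescaled to the same RPKM total, and -0.289 with the haemoglobin share alone given back. The infected difference was 1.06 (SE 0.36, adjusted p = 0.0302; 0.00183 to 0.903 over 21 alternatives). Without myeloid knockout infected replicate 1 or 2, or wild-type infected replicate 2, that difference did not pass. The labels do not give which exons the allele lacks, so a value over the whole gene cannot check the genotype. Every genotype direction here rests on the labels. Il27ra, higher by label in spleen and in infected myeloid cells, neither bears them out nor counts against them.

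**Figure D1:**
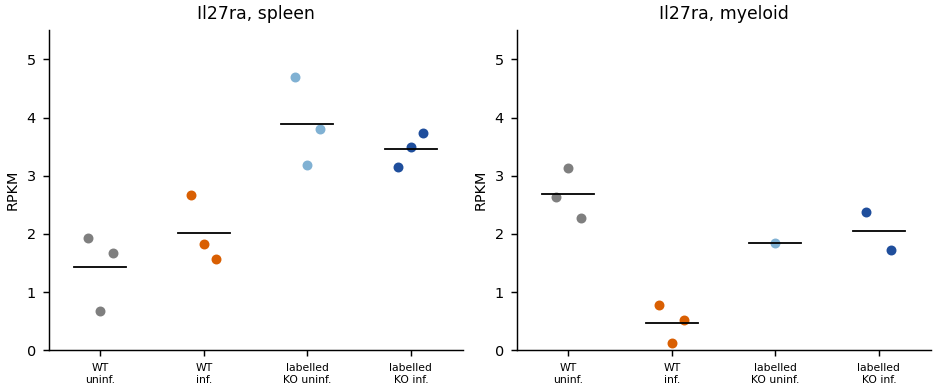
Il27ra in each library, in RPKM, for spleen and for myeloid cells, with points for libraries and lines for group means. In spleen the libraries labelled knockout lay between 3.15 and 4.7 RPKM and the wild-type libraries between 0.673 and 2.67 RPKM.

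Infection of wild-type pups raised acute-phase, cytokine and chemokine transcripts in spleen within 24 hours. Saa3, an acute-phase serum amyloid A protein (chromosome 7, 46711998 to 46715700), rose from 0.125 ± 0.216 to 1966 ± 247.3 RPKM (SD, n = 3 per group), a log2 fold change of 10.78 (SE 0.253, adjusted p = 5.87e-11). The inflammatory cytokines Il1b (chromosome 2, 129364570 to 129371139) and Il1a (chromosome 2, 129299610 to 129309972) rose by 5.24 (SE 0.321) and 5.14 (SE 0.202) on the log2 scale, to 86.3 ± 32.2 and 122.1 ± 36.1 RPKM. The protease inhibitor gene Serpina3n (chromosome 12, 104406729 to 104414329) rose by 5.75 (SE 0.324), the copper-carrying plasma protein gene Cp (chromosome 3, 19957054 to 20009145) by 4.89 (SE 0.213) and the chemokine gene Ccl12 (chromosome 11, 82101845 to 82103400) by 5.03 (SE 0.29). The stress-response pseudokinase gene Trib3 (chromosome 2, 152337422 to 152344032) rose by 5.08 (SE 0.403) and the NF-kB feedback inhibitor gene Tnip3 (chromosome 6, 65525313 to 65634040) by 4.91 (SE 0.152).

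The genes that fell most in infected wild-type spleen included single genes of the extracellular matrix and of neutrophils. The list of stromal and fibroblast genes did not move as a group (1 of 20 fell and 3 rose, the same when adjusted over the list alone; camera adjusted p = 0.598). Edn3, an endothelin peptide gene (chromosome 2, 174760619 to 174784042), fell by 2.77 (SE 0.151), from 14.0 ± 1.06 to 1.21 ± 0.299 RPKM (SD, n = 3). The elastic-fibre gene Fbln5 (chromosome 12, 101746565 to 101819055) changed by -2.41 (SE 0.18), the integrin gene Itga8 (chromosome 2, 12106632 to 12301922) by -2.46 (SE 0.257), the neutrophil gene Retnlg (chromosome 16, 48872621 to 48874496) by -2.28 (SE 0.196), and Angptl7 (chromosome 4, 148495183 to 148500460), Crabp1 (chromosome 9, 54764748 to 54773110) and Pdlim3 (chromosome 8, 45885461 to 45919548) by -2.60, -2.47 and -2.22. Ly6g (chromosome 15, 75155240 to 75159126), a surface marker of mouse neutrophils, was at 9.18 ± 2.30 RPKM in uninfected wild-type spleen and was listed at 0 in all 3 infected libraries.

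The interferon and inflammation lists moved together. Of 31 type I interferon-stimulated genes, 27 rose and 0 fell (29 and 0 when adjusted over the list alone), among them Ifit1 by 3.49, Usp18 by 2.72 and Rsad2 by 1.91. Of 22 chemokines 15 rose and 1 fell (17 and 1 adjusted over the list alone), with Ccl3 higher by 4.39 and Cxcl10 by 2.75. Of 15 acute-phase genes 11 rose, the same count when adjusted over the list alone. Of 23 NF-kB targets and feedback regulators 17 rose (18 adjusted over the list alone), Nfkbia by 2.53 and Tnfaip3 by 3.03. Of 18 glucocorticoid-response genes 15 rose (15 adjusted over the list alone), including Il1r2, a decoy receptor for IL-1, by 3.90 and Pdk4 by 3.21. The camera test placed these 5 lists above other genes with adjusted p between 1.6e-30 and 3.8e-17, and each call held with an estimated correlation (largest adjusted p = 0.0408).

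The cytokine lists rose on both sides of the inflammatory balance. Of 13 proinflammatory cytokines 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Csf3, the granulocyte growth factor, up by 3.82 (camera adjusted p = 7.13e-08; 0.0314 with an estimated correlation). Of 16 anti-inflammatory mediators 11 rose and 2 fell (11 and 4 adjusted over the list alone), with Il10 up by 2.68, the IL-1 receptor antagonist gene Il1rn by 3.18 and Cd274, which encodes PD-L1, by 2.60 (camera adjusted p = 7.17e-07; 0.0195 with an estimated correlation). Of 13 genes reported to respond to IL-27, 8 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 3.02e-07; 0.0408 with an estimated correlation). With the replicate number as a block among the wild-type spleens, the estimated-correlation calls of the proinflammatory and IL-27 lists were lost (adjusted p = 0.0517 and 0.0926). Of 23 interferon-gamma and GTPase response genes, 13 rose and 1 fell (18 and 1 adjusted over the list alone), Tgtp2 by 3.40, with camera adjusted p = 2.45e-14 but adjusted p = 0.121 with an estimated correlation.

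Lists of cell types and other processes were also tested. Of 24 mature neutrophil genes 12 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 6.45e-11; 0.0408 with an estimated correlation), and of 29 pattern-recognition genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 6.53e-12), led by the scavenger receptor gene Marco, up by 4.39, the lipopolysaccharide co-receptor gene Cd14, up by 3.98, and Clec4e, up by 3.87. With the block both lists had adjusted p = 0.0712 with an estimated correlation, against 0.0408 without it. Of 14 primary granule and promyelocyte genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone), with the elastase gene Elane at -2.20 and Fcnb at -2.11 (camera adjusted p = 0.000224; adjusted p = 0.22 with an estimated correlation). Of 40 cell cycle genes 11 fell and 1 rose (19 and 2 adjusted over the list alone), including E2f1 at -0.97 and Mcm4 at -0.79 (camera adjusted p = 0.000436; adjusted p = 0.17 with an estimated correlation). Of 22 iron and haem genes, 9 rose and 5 fell (11 and 6 adjusted over the list alone): the iron exporter gene Slc40a1 stood at -1.78 (SE 0.1) and Spic, a haem-induced transcription factor of red pulp macrophages, at 2.22 (SE 0.17). Exocrine pancreas transcripts, a sign of neighbouring tissue, varied widely within groups: their mean log2 value was 0.313, 6.2 and 2.99 in the uninfected and 0.366, 5.51 and 0.524 in the infected wild-type spleens, and 0 of the 19 pancreas genes tested passed (limma; camera adjusted p = 0.602).

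With limma, 923 genes rose and 935 fell among 12063 tested (adjusted p below 0.05), and 436 of those that rose and 187 of those that fell changed at least 2-fold. Median-ratio scaling gave 1178 higher and 741 lower. Fitting the 6 wild-type libraries alone gave 944 genes, 584 higher and 360 lower. Leaving out wild-type uninfected replicate 3 gave 1223, 727 higher and 496 lower. Leaving out wild-type infected replicate 3 gave 781 higher and 513 lower, and infected replicate 1 gave 849 and 1277. The groups did not overlap for 3435 genes, where chance gives 10%.

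**Figure D2:**
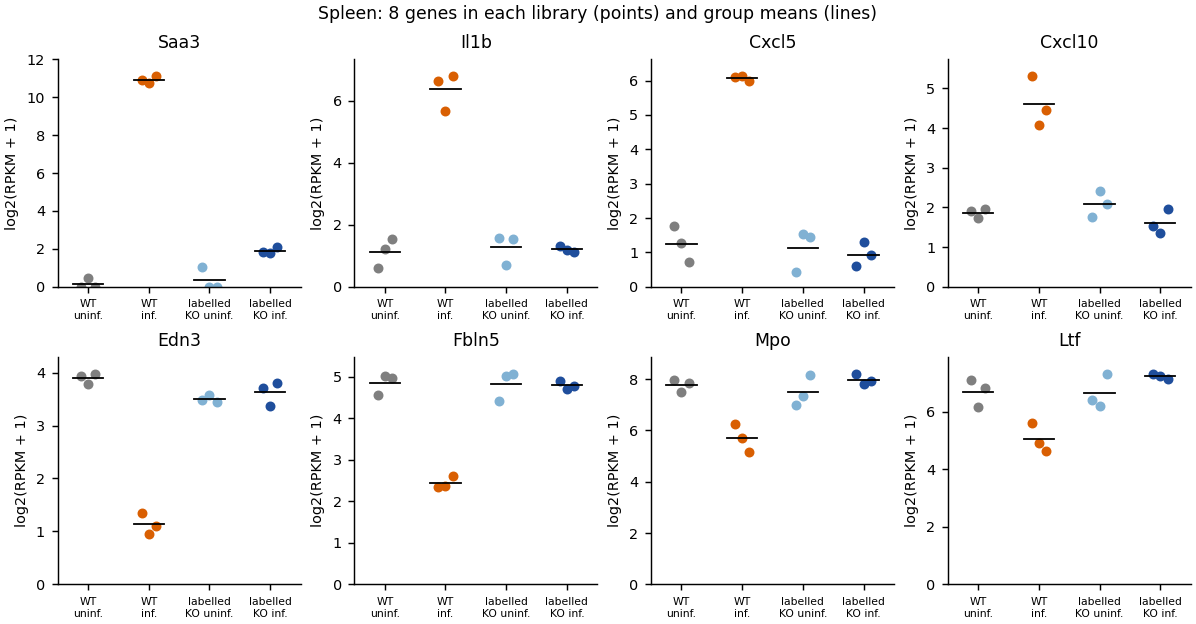
Log2(RPKM + 1) of 8 genes in the 12 spleen libraries, with points for libraries and lines for group means, by genotype label and infection. Saa3, Il1b, Cxcl5 and Cxcl10 stood apart in the 3 infected wild-type libraries, as did the lower values of Edn3, Fbln5, Mpo and Ltf; Saa3 averaged 1966 RPKM there and 2.76 RPKM in infected spleens labelled knockout.

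Infected spleens labelled knockout showed little of this response. Saa3 stood at 2.76 ± 0.425 RPKM against 0.365 ± 0.632 RPKM without infection (SD, n = 3), a rise of 1.55 (SE 0.253, adjusted p = 0.0369). Il1b was at 1.51 ± 0.759 RPKM without and 1.32 ± 0.14 RPKM with infection, and Il1a at 1.96 ± 0.347 and 2.89 ± 0.249 RPKM. The genes that rose most included Ifitm6 (chromosome 7, 141015699 to 141017924; 1.71, SE 0.212, adjusted p = 0.00945), an interferon-induced transmembrane protein gene; Dgat2, a triglyceride synthesis enzyme gene (chromosome 7, 99153658 to 99182719; 1.67); Ms4a6d (chromosome 19, 11586604 to 11604849; 1.35); the myeloid receptor gene Clec5a (chromosome 6, 40574894 to 40585821; 1.30); and Hp, which encodes haptoglobin (chromosome 8, 109575128 to 109579172; 1.25). Cd5l, Ccr1 and Gca rose by 1.16, 1.15 and 1.15. Ly6g stood at 10.4 ± 3.88 RPKM without and 2.59 ± 0.764 RPKM with infection, a change of -1.63 (adjusted p = 0.0295).

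Few lists passed in these spleens by gene. Of 24 mature neutrophil genes 0 passed over all genes tested and 12 rose adjusted over the list alone, with Cxcr2 at 0.96 (adjusted p = 0.0906) and Stfa2 at 0.97 (adjusted p = 0.11). Of 29 pattern-recognition genes 0 passed, and 11 rose and 2 fell adjusted over the list alone. Of 14 primary granule genes 0 passed, and 6 rose and 1 fell adjusted over the list alone, with Ms4a3 at 1.10 (adjusted p = 0.0906). The camera test called these 3 lists higher (adjusted p = 1.89e-11, 1.09e-08 and 0.000371), but with an estimated correlation adjusted p = 0.223, 0.223 and 0.422. Cxcr2, Stfa2 and Ms4a3 each passed in some of 25 alternatives. Their adjusted p ranged from 0.0451 to 0.583, from 0.0126 to 0.68 and from 0.0215 to 0.589. The mean log2 value of pancreas genes was 0.291, 0.381 and 5.74 in the uninfected and 5.82, 2.81 and 0.313 in the infected spleens labelled knockout. With limma, 14 genes rose and 1 fell, against 718 at an unadjusted p below 0.05. The count was 8 with the pancreas score as a covariate and 10 with no filter on low values. It was 2, 1 and 1 without infected replicate 1, 2 and 3 labelled knockout, and between 1 and 24 over all 12 omissions. Of the 14 genes that rose, 10 also rose in wild type, where 1.07 would be shared by independent lists (one-sided Fisher exact p = 4.95e-09, adjusted p = 1.24e-08 over 10 overlaps).

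The test of the difference between the responses called 603 genes. The response of Saa3 was smaller in the libraries labelled knockout, with a difference of -9.23 (SE 0.358, adjusted p = 3.13e-08). So were those of Il1b at -5.31 (SE 0.453), the neutrophil-attracting chemokine gene Cxcl5 (chromosome 5, 90759360 to 90761624) at -5.03 (SE 0.438), Serpina3n at -5.02, Tnip3 at -4.78 and Il1a at -4.74. Acod1, the itaconate-producing enzyme gene (chromosome 14, 103046977 to 103056573), stood at -4.61 and Serpina3f (chromosome 12, 104214544 to 104221129) at -4.58. In the other direction stood Angptl7 (3.17), Edn3 (2.89), Crabp1 (2.60), the matrix gene Olfml3 (chromosome 3, 103722222 to 103738001; 2.59), the neutrophil granule genes Mpo (chromosome 11, 87793581 to 87804413; 2.54) and Ltf (chromosome 9, 111019271 to 111042767; 2.25), Fbln5 (2.37) and Pdlim3 (2.28), most of which were lower with infection in wild type. Mpo, the myeloperoxidase gene, stood at 219.4 and 53.8 RPKM without and with infection in wild type and at 191.2 and 253.1 RPKM in the libraries labelled knockout.

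By list, 24 of 31 type I interferon-stimulated genes responded less and 0 more in the libraries labelled knockout (28 and 0 adjusted over the list alone; camera adjusted p = 4.65e-35), with Ifit1 at -3.21 and Usp18 at -3.17. So did 12 of 22 chemokines, with 1 the other way (16 and 1 adjusted over the list alone; Ccl3 at -4.18), 11 of 18 glucocorticoid-response genes (14 adjusted over the list alone; Pdk4 at -3.14), 8 of 15 acute-phase genes (8 adjusted over the list alone), 6 of 13 proinflammatory cytokines (7, and 1 the other way, adjusted over the list alone; Csf3 at -3.91) and 6 of 23 apoptosis and p53 genes (7 adjusted over the list alone). Among 13 genes reported to respond to IL-27, 7 responded less and 2 more (10 and 2 adjusted over the list alone), and among 16 anti-inflammatory mediators 6 less and 2 more (7 and 4 adjusted over the list alone; Il1rn at -3.69). These 8 calls held with an estimated correlation (largest adjusted p = 0.039). The interferon-gamma list, with 12 of 23 genes responding less (17, and 1 the other way, adjusted over the list alone), and the NF-kB list, with 8 of 23 (17 adjusted over the list alone), had adjusted p = 0.0958 and 0.0636 with an estimated correlation. Of 14 primary granule genes 8 responded more and 1 less (10 and 1 adjusted over the list alone), Elane at 2.11 and the proteinase 3 gene Prtn3 at 1.98, with adjusted p = 0.111 with an estimated correlation.

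With limma, 222 genes differed upward and 381 downward in the response (labelled knockout minus wild type), against 2210 at an unadjusted p below 0.05, and 393 passed with a mean of at least 5 RPKM. Without infected replicate 1 or 3 labelled knockout 399 passed. Without wild-type infected replicate 1, 869 did, 452 upward and 417 downward. The upward count was 117 to 131 without wild-type uninfected replicate 3, uninfected replicate 1 labelled knockout, or infected replicate 1 or 3 labelled knockout. Over the 923 genes that rose in wild type the median change was 0.965 in wild type and 0.0861 in the libraries labelled knockout, and 380 of them passed the test of the difference; over the 935 that fell the medians were -0.676 and -0.0503, with 208 passing. These genes were chosen on the wild-type libraries, which enter both tests.

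**Figure D3:**
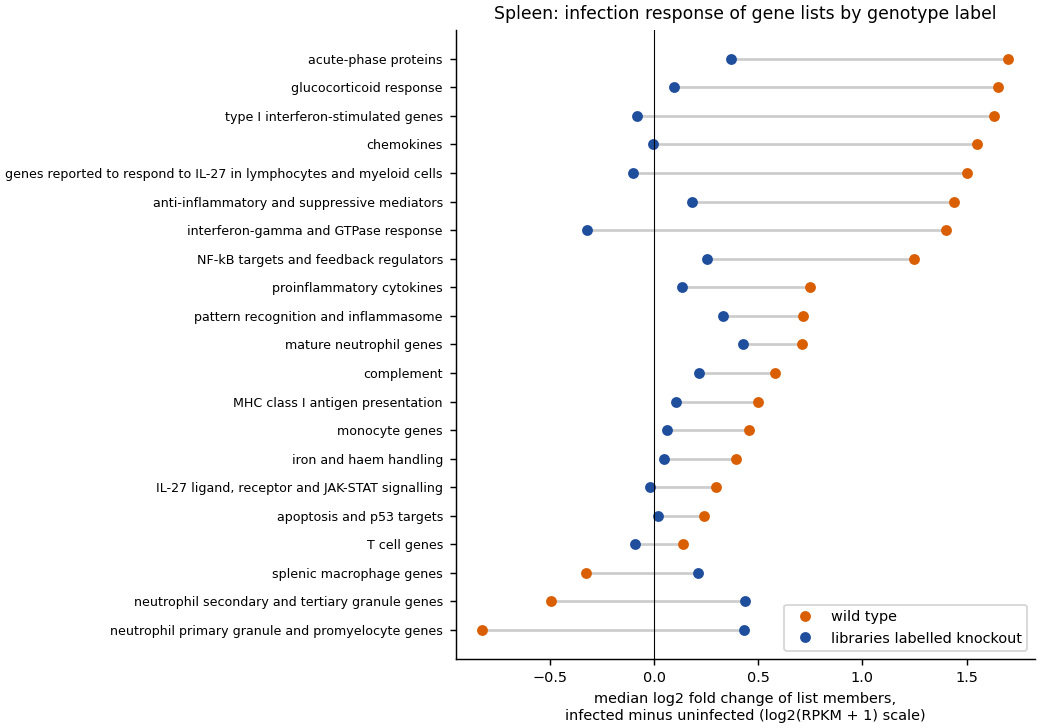
Median log2 fold change with infection in spleen for the members of 21 gene lists, as orange points for wild type and blue points for libraries labelled knockout, joined by a line. The median of type I interferon-stimulated genes was 1.63 in wild type, and that of primary granule genes was -0.83 in wild type and 0.43 in libraries labelled knockout.

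Without infection, few genes were called between the spleens of the 2 labelled genotypes. Clgn, which encodes a calnexin-like endoplasmic reticulum chaperone (chromosome 8, 83389867 to 83428552), stood at 6.74 RPKM in wild type and 0.544 RPKM in the libraries labelled knockout (-2.33, SE 0.18, adjusted p = 0.000144), and Car1, the carbonic anhydrase 1 gene of red cells (chromosome 3, 14766216 to 14808368), at 390.9 and 133.3 RPKM (-1.55, SE 0.198, adjusted p = 0.0104). Wdfy1 (chromosome 1, 79702262 to 79776143) was at 2.53 and 11.7 RPKM (1.86, SE 0.16, adjusted p = 0.000251) and Efcab7 (chromosome 4, 99829198 to 99912788) at 2.18 and 7.70 RPKM (1.46, SE 0.175, adjusted p = 0.00707). The mitochondrial transhydrogenase gene Nnt (chromosome 13, 119335448 to 119408997), which carries a deletion in the C57BL/6J substrain, stood at 5.26 and 12.1 RPKM (1.05, SE 0.165, adjusted p = 0.0672). It passed with another scaling (adjusted p = 0.0459 with median ratios and 0.0379 with quantiles), and over 25 alternatives its adjusted p ranged from 0.0123 to 0.331. It also passed without wild-type infected replicate 3 (adjusted p = 0.0431), with the GC trend removed (adjusted p = 0.0289) and with the pancreas score (adjusted p = 0.0123). Of 20 T cell genes 0 passed over all genes, 8 were lower adjusted over the list alone, with Cd3g at -1.05 (adjusted p = 0.178) and Trbc2 at -0.85 (adjusted p = 0.189), and the camera call (adjusted p = 2.57e-06) was lost with adjusted p = 0.833 with an estimated correlation. With limma 2 genes were higher and 2 lower in the libraries labelled knockout, against 1406 at an unadjusted p below 0.05. Fitting the 6 uninfected libraries alone gave 2. Without wild-type uninfected replicate 1 the count was 25, without wild-type uninfected replicate 3 or uninfected replicate 2 labelled knockout Efcab7 and Car1 no longer passed, and without uninfected replicate 3 labelled knockout Car1 did not.

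**Figure D4:**
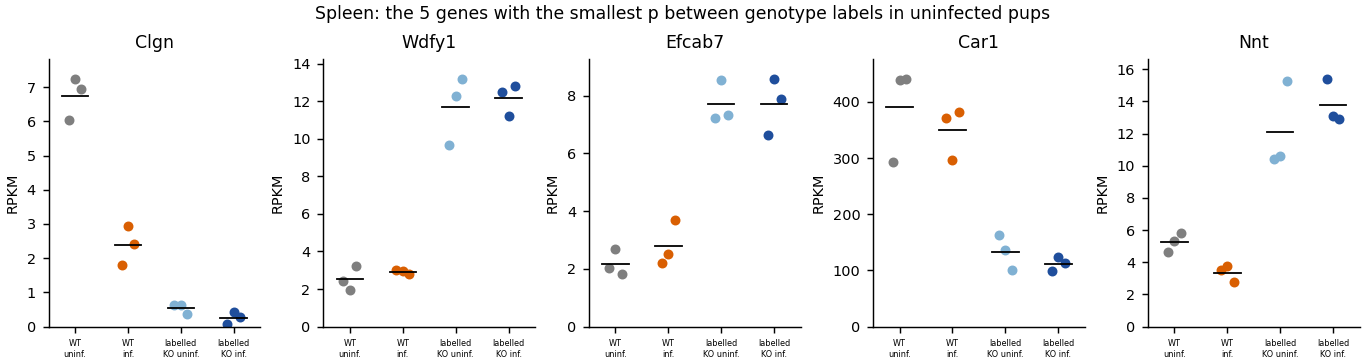
RPKM of Clgn, Wdfy1, Efcab7, Car1 and Nnt in the 12 spleen libraries, with points for libraries and lines for group means. For each gene the libraries labelled knockout lay on the same side of the wild-type libraries with and without infection, for example 11.7 and 12.2 RPKM on average for Wdfy1 against 2.53 and 2.94 RPKM.

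In infected spleen the labelled genotypes differed in 3358 genes. Saa3 was at 1966 ± 247.3 RPKM in wild type and 2.76 ± 0.425 RPKM in libraries labelled knockout (SD, n = 3; -9.03, SE 0.253, adjusted p = 5.44e-10). Il1b, Cxcl5, Il1a, Tnip3, Acod1, Serpina3n and Cp were lower, at -5.16, -5.15, -4.94, -4.87, -4.61, -4.58 and -4.57. Angptl7, Edn3, Fbln5, Mpo, Olfml3 and Ltf were higher by 2.68, 2.49, 2.36, 2.27, 2.22 and 2.18, and the gelatinase gene Mmp9 (chromosome 2, 164940780 to 164955850) and Retnlg by 2.08 and 2.07. Of 31 type I interferon-stimulated genes 28 were lower (30 adjusted over the list alone), of 22 chemokines 17 lower and 1 higher (18 and 1 adjusted over the list alone), and of 18 glucocorticoid-response genes 15 lower (15 adjusted over the list alone), with camera adjusted p between 1.1e-25 and 1.12e-15 and all 3 held with an estimated correlation (largest adjusted p = 0.0339). Of 20 T cell genes 10 were lower and 0 higher (11 and 0 adjusted over the list alone), with Trbc2 at -1.63, Cd3g at -1.53, Il7r, the IL-7 receptor gene, at -1.46 and Tcf7 at -1.06 (camera adjusted p = 1.35e-07; adjusted p = 0.122 with an estimated correlation). Of 14 primary granule genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 2.97e-05; adjusted p = 0.181 with an estimated correlation), and of 40 cell cycle genes 18 were higher and 2 lower (21 and 4 adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.436 with an estimated correlation). The genes of the uninfected comparison kept their direction: Clgn at -1.42 (adjusted p = 0.000176), Wdfy1 at 1.74 and Nnt at 1.77 (adjusted p = 1.27e-05).

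With limma 2171 genes were higher and 1187 lower in infected spleens labelled knockout. The split depended on the scaling: median ratios, which moved the median over all genes from 0.132 to -0.003, gave 1583 higher and 1796 lower, and removal of a GC trend per library, chosen after seeing the data, gave 1444 and 1353. The fold change correlated with GC content across genes (Spearman 0.48 over genes, which are not independent replicates). Leaving out 1 library gave between 1597 and 4266 genes. The count was 1597 (814 higher and 783 lower) without wild-type infected replicate 3. It was 1655 (911 and 744), 1869 (1096 and 773) and 2052 (1197 and 855) without infected replicates 1, 2 and 3 labelled knockout. Without wild-type infected replicate 1 it was 4266 (2972 and 1294), so the split depended on single libraries too.

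Few genes were called for infection in enriched myeloid cells of wild-type pups. Prok2, which encodes a neutrophil-expressed secreted peptide (chromosome 6, 99711299 to 99726392), rose from 0.13 ± 0.168 to 125.3 ± 30.6 RPKM (SD, n = 3; 6.78, SE 0.357, adjusted p = 2.76e-05). The pentraxin gene Ptx3 (chromosome 3, 66219910 to 66225805) rose by 6.48 (adjusted p = 0.00329), the lipase gene Lipg (chromosome 18, 74939322 to 74961263) by 5.95, Acod1 by 4.37, the chemokine gene Cxcl2 (chromosome 5, 90903871 to 90905938) by 4.36, Il1r2 by 4.24, Matn3 (chromosome 12, 8947929 to 8972028) by 3.82 and the osteopontin gene Spp1 (chromosome 5, 104435118 to 104441050) by 3.58. Among the genes that fell were the adhesion molecule gene Vcam1 (chromosome 3, 116109949 to 116129688) at -4.07 (adjusted p = 0.00457), Slc40a1 (chromosome 1, 45908068 to 45926523) at -3.05 and the mannose receptor gene Mrc1 (chromosome 2, 14229392 to 14332057) at -2.91. Hpgd (chromosome 8, 56294585 to 56321043) stood at -2.74 and the lysozyme gene Lyz2 (chromosome 10, 117277331 to 117282321) at -2.74. The eotaxin receptor gene Ccr3 (chromosome 9, 124021972 to 124031689), Nrp1 (chromosome 8, 128358604 to 128503363) and Xlr4b (chromosome X, 73214333 to 73222453) were lower at -4.06, -2.90 and -2.86.

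Of 24 mature neutrophil genes 6 rose and 0 fell in these cells (15 and 0 adjusted over the list alone), with the calprotectin subunit gene S100a9 up by 1.45 and the stefin gene Stfa2 up by 2.61 (camera adjusted p = 1.07e-26; adjusted p = 0.0586 with an estimated correlation). Of 13 acute-phase genes 2 rose (7 adjusted over the list alone), and of 25 chemokines 2 rose (5 adjusted over the list alone), with adjusted p = 0.114 and 0.184 with an estimated correlation. Of 25 splenic macrophage genes 3 fell (7 adjusted over the list alone; camera adjusted p = 1.43e-06; adjusted p = 0.184 with an estimated correlation). Mean log2 values of Y-linked genes were 0, 0.054 and 0.197 in the uninfected and 4.08, 1.69 and 0.0352 in the infected wild-type libraries. With that score as a covariate 40 genes passed, of which 21 were among the 39 called without it. Acod1, Cxcl2, Il1r2, Matn3, Spp1 and S100a9 did not pass, with changes of 4.29, 4.10, 4.18, 2.58, 2.91 and 1.29. With limma 22 genes rose and 17 fell among 14120, against 1424 at an unadjusted p below 0.05. A fit of only the 2 groups compared gave 10 higher and 2 lower. Most falls were thus called only with a spread shared with the libraries labelled knockout. Median ratios gave 32 and 12, quantiles, which moved the median over all genes from -0.184 to -0.005, gave 20 in all, and removal of a GC trend gave 30 and 12. Haemoglobin genes removed and every library rescaled to the same total gave 18 and 43, and their share alone given back gave 22 and 17. Il1r2, Matn3 and S100a9 did not pass with no filter on low values, and the count was 14 without either infected replicate labelled knockout, 18 and 19 without uninfected wild-type replicates 3 and 1, and 25 without infected wild-type replicate 2. Of the 20 genes that rose and were tested in both tissues, 17 also rose in wild-type spleen, against 1.51 for independent lists (one-sided Fisher exact p = 6.99e-17, adjusted p = 6.99e-16 over 10 overlaps), and of 14 that fell 10 also fell there, against 1.04 (exact p = 3.65e-09, adjusted p = 1.22e-08).

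In the myeloid libraries labelled knockout, infection was compared with 1 uninfected library, which was assumed to vary like the other groups. The groups did not vary alike: the variance between libraries over sampling noise was 13.18 to 22.9 in wild-type pairs and 3.62 in the infected pair labelled knockout. P-values that use the pooled spread are therefore uncertain here, between genotype labels and for infection in wild type. Ifitm6 stood at 48.6 RPKM without and 559.7 ± 205.6 RPKM with infection (SD, n = 2; 3.45, SE 0.464, adjusted p = 0.0373), and S100a9 at 1342 and 7483 ± 1839 RPKM (2.46, SE 0.282, adjusted p = 0.0292). The other rule-named genes were the stefin genes Stfa2, Stfa1, BC100530 and Stfa2l1 on chromosome 16, with rises of 2.70, 2.45, 2.43 and 2.25. These genes are near-identical copies among which reads can be split, so their values are uncertain. Of 24 mature neutrophil genes 5 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 2.29e-26; adjusted p = 0.0619 with an estimated correlation), and of 36 erythroid genes 0 passed, in all genes or adjusted over the list alone (median -1.11; camera adjusted p = 9.93e-27; adjusted p = 0.12 with an estimated correlation), while haemoglobin genes made up 8.0% of the RPKM total in the uninfected and 3.4% and 4.1% in the infected libraries. The Y-linked mean was 0.0093 in the uninfected and 3.37 and 2.89 in the infected libraries. With limma 8 genes rose and 0 fell, against 426 at an unadjusted p below 0.05, and 6 of the 8 also rose in wild type. The 8 include near-identical stefin genes, and both responses share 1 estimate of the spread per gene, so no p-value is given for that overlap. The count was 0 with median ratios, with a pseudocount of 0.1, with a mean of at least 5 RPKM, with the Y-linked score as a covariate, or without any library other than infected wild-type replicate 3, whose omission gave 10; without the uninfected library labelled knockout there is no comparison.

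**Figure D5:**
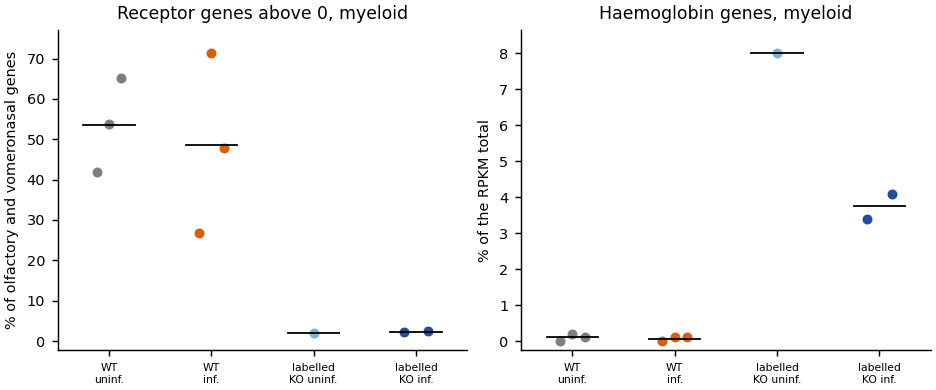
Percent of olfactory and vomeronasal receptor genes detected above 0, on the left, and percent of the RPKM total held by haemoglobin genes, on the right, in each myeloid library, with points for libraries and lines for group means. Wild-type libraries detected 26.8% to 71.3% of receptor genes and libraries labelled knockout 2.1% to 2.4%.

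Between genotype labels the myeloid libraries differed in background as well as in gene expression. Olfactory and vomeronasal receptor genes were detected at 26.8% to 71.3% in the wild-type libraries and at 2.1% to 2.4% in those labelled knockout, against 1.1% to 2.3% in spleen. The 10 most abundant genes held 35.2% to 59.7% of the RPKM total in wild type and 12.2% to 14.8% in the libraries labelled knockout, and haemoglobin genes held 0.0% to 0.2% and 3.4% to 8.0%. Eef2, a translation elongation factor gene of every cell (chromosome 10, 81176631 to 81182498), stood at 0.721 and 1.3 RPKM in uninfected and infected wild type and at 917.9 and 1062 RPKM in the libraries labelled knockout (9.06 and 8.85 higher, SE 0.432 and 0.342).

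Erythroid transcripts were among the higher genes in the libraries labelled knockout. The red-cell anion exchanger gene Slc4a1 (chromosome 11, 102348824 to 102366203) was higher by 9.40 (SE 0.584) without and 8.97 (SE 0.462) with infection, and Hbb-bs, a beta-globin gene (chromosome 7, 103826534 to 103828096), by 8.10 and 7.85. Of 36 erythroid genes 33 were higher and 0 lower in each comparison (34 and 33 adjusted over the list alone), and of 40 cell cycle genes 28 and 31 (30 and 31 adjusted over the list alone), with adjusted p = 0.954 and 0.703 with an estimated correlation for both lists. Mast cell protease gene Mcpt4 (chromosome 14, 56059629 to 56062313) was higher by 8.25 and 8.79, and in uninfected cells so were Ube2l6, Grina and Pigq by 8.23, 7.82 and 7.76. With infection Tpsb2, a mast cell tryptase gene, and Ppp1ca were higher by 8.30 and 7.94. Of 25 splenic macrophage genes 21 were higher and 1 lower in infected cells (22 and 1 adjusted over the list alone; camera adjusted p = 0.00879; adjusted p = 0.703 with an estimated correlation), with the complement gene C1qa at 5.05.

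Some chemokine genes and genes of the stefin cluster were lower there. Of 25 chemokines 7 were lower and 1 higher without infection and 11 and 2 with it (6 and 1, and 11 and 2, adjusted over the list alone; adjusted p = 0.954 and 0.703 with an estimated correlation). Ccl4 (chromosome 11, 83662584 to 83664683) was lower at -7.14 and -7.03, and with infection Ptx3 and Il6 (chromosome 5, 30013114 to 30019981) at -7.15 and -6.70. The stefin-cluster genes BC100530, Stfa1 and BC117090, near-identical copies whose values are uncertain, stood at -8.89, -8.38 and -8.19 without infection. The symbol deb1, which matched no gene of the annotation, was at -8.77, Chmp5 at -6.95, Rsl24d1 at -6.82 and Cd53 at -6.79. Nnt, higher by label in spleen, was lower in these cells at -3.94 without infection, with 1 library labelled knockout, and at -1.88 with infection (adjusted p = 0.00803). Wdfy1 stood at -0.32 without infection and at 1.37 with it (adjusted p = 0.0173), the latter in the direction seen in spleen. Clgn, Efcab7 and Car1 stood at -0.43, -0.24 and 0 with infection, and none of them passed.

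With limma 4011 genes were higher and 979 lower without infection, which rests on 1 library labelled knockout, and 6010 higher and 939 lower with infection. Quantile normalization gave 1841 and 1594, and 2467 and 2010. Median ratios moved the median over all genes in infected cells from 0.838 to 0.074 and gave 4107 and 1515, and removal of a GC trend gave 4696 and 1593. Without infected replicate 1 labelled knockout 4725 genes passed. Genotype label and library background separate the same libraries, so they cannot be told apart here. The test of the difference in infection response called 0 genes with limma, against 467 at an unadjusted p below 0.05. The 5 smallest p belonged to Prok2 (-3.90), Ccr3 (3.53), Xlr4b (3.36), Ptx3 (-6.57) and Nrp1 (3.32), each with adjusted p = 0.656. In simulated data with these groups that test recovered 0% of genes with a true log2 difference of 2 and 23.3% at 4, so a count of 0 says little at this size. The simulation gave a gene the same spread in every group, which the real myeloid libraries did not have, so these shares are rough.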

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

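In this part the split of the labelled knockout spleens between uninfected and infected, the test of genes around Il27ra and the counts over other splits were planned, and the tests of pancreas RNA, infection strength, genes shared with wild type, GC trend, haemoglobin, receptor genes, called genes outside the region and exchanged labels were chosen only after the result was seen.

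The first pattern is that infected spleens labelled knockout showed little of the wild-type response, with 603 genes in the test of the difference. Pancreas RNA is argued against as the cause, since 516 genes passed with the pancreas score as a covariate. A weaker infection in the pups labelled knockout stays open: the slope of their change on the wild-type change, over genes raised in wild type, was 0.0994, and bacterial load was not used here. That the infected libraries labelled knockout all came from uninfected pups stays open as well. Of the 14 genes that rose, 10 also rose in wild type, against 1.07 for independent lists (one-sided Fisher exact p = 4.95e-09). That test takes genes as independent and does not measure the spread between libraries. Only 2, 1 and 1 genes passed without infected replicates 1, 2 and 3 labelled knockout. The planned count of splits could not decide it either. Of 10 splits 1 gave a slope as large (0.0994, highest other 0.0743), and 10 are too few for a share under 0.05. The genotype itself cannot be told apart from a weaker or absent infection.

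The second pattern is that 6949 genes differed between genotype labels in infected myeloid cells. A GC trend is argued against as the whole cause, since 6289 genes passed with the trend removed. Haemoglobin transcripts are argued against too. Their highest share in a library labelled knockout, 8% of the RPKM total, would change other genes by -0.12 on the log2 scale. With their share alone given back 6128 genes were higher in the libraries labelled knockout, against 6010 before. The count of higher genes alone is no test, since it depended on the scaling (4107 with median ratios and 2467 with quantiles). A difference in library preparation is consistent with the receptor genes detected, at least 26.8% in each wild-type library. The genotype itself cannot be told apart from it, because every library labelled knockout was at or below 2.4%.

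The third pattern is that few genes differed between uninfected spleens, with Clgn and Nnt among those with the smallest p. Strain variants carried with the targeted allele may explain part of it. Within 10 Mb of Il27ra 28 of 109 genes (25.7%) had an unadjusted p below 0.05, against 1340 of 11679 elsewhere (11.5%, one-sided Fisher exact p = 3.42e-05). After adjustment 1 of the 109 passed. The Fisher test takes genes as independent. The fold change also correlated with GC content (Spearman 0.37 over genes), which was not compared between that region and elsewhere. Strain variants that change only genes within the region are argued against as the cause for every gene. Of the called genes, 3 (Wdfy1, Efcab7 and Car1) lie outside the region. Their position cannot speak to variants there that change genes elsewhere, which stays untested. An exchange of genotype labels between uninfected spleens is argued against, since 5 of 5 genes separated infected spleens by label in the same direction. An exchange of the labels of all spleens would give the same result, so this test cannot speak to it. A difference in C57BL/6 substrain stays open as untested. In infected myeloid cells Nnt went the other way by label (-1.88) and Wdfy1 the same way (1.37). Clgn, Efcab7 and Car1 stood at -0.43, -0.24 and 0 there. Genotype label and library background cannot be told apart in those cells, so these values do not decide it.

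The splits of 3 against 3 libraries are too few for a share under 0.05. Mixed splits also carry any real difference in their spread within groups, so a low count there cannot show what chance gives. The real grouping was the 1 split as large as itself in each of 5 counts: 1858 genes for infection in wild-type spleen (highest other 0), 15 for infection in spleens labelled knockout (1), 4 for genotype label in uninfected spleen (2), 3358 in infected spleen (0) and 39 for infection in wild-type myeloid cells (5). For the 603 genes of the difference in spleen 11 of 100 splits were as large, the highest at 3906. All 11 were among the 15 splits that kept the infected libraries grouped by genotype label and so still held that difference, which makes this planned count void as a test of chance, a reason found only after it was seen. The large counts point to that structure of the samples. Splits that mixed the infected libraries gave at most 0. Mixing puts the difference between labels into the spread within groups, so that 0 cannot show what chance gives either.

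A test of the difference between responses set apart these spleen genes (labelled knockout minus wild type): Angptl7 3.17, Edn3 2.89, Crabp1 2.60, Olfml3 2.59, Mpo 2.54, Fbln5 2.37, Pdlim3 2.28, Ltf 2.25, Saa3 -9.23, Il1b -5.31, Cxcl5 -5.03, Serpina3n -5.02, Tnip3 -4.78, Il1a -4.74, Acod1 -4.61 and Serpina3f -4.58. The lists set apart in spleen whose call held with an estimated correlation had medians of -1.66 (type I interferon-stimulated genes), -1.64 (chemokines), -1.51 (glucocorticoid response), -1.43 (acute-phase proteins), -1.14 (genes reported to respond to IL-27), -0.92 (proinflammatory cytokines), -0.79 (anti-inflammatory mediators) and -0.25 (apoptosis and p53 targets). Those whose call was lost were -1.51 (interferon-gamma and GTPase response), -1.11 (NF-kB targets), -0.49 (pattern recognition), -0.45 (MHC class I), -0.45 (complement), -0.42 (IL-27 ligand, receptor and JAK-STAT signalling), -0.39 (iron and haem), -0.35 (monocyte), -0.21 (T cell), 0 (mature neutrophil, with members both ways), 0.42 (splenic macrophage), 0.88 (secondary and tertiary granule) and 1.22 (primary granule).

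In myeloid cells 17 lists were set apart, and all 17 calls were lost with an estimated correlation (adjusted p from 0.211 to 0.564). Their medians were 1.42 (splenic macrophage), 1.37 (eosinophil), 1.21 (monocyte), 1.13 (B cell), 1.03 (mast cell and basophil), 1.02 (dendritic cell), 0.98 (MHC class II), 0.96 (glycolysis and hypoxia), 0.94 (stem and progenitor), 0.81 (T cell), 0.78 (pattern recognition), 0.75 (unfolded protein response), -0.05 (apoptosis and p53 targets), -0.12 (cell cycle), -0.21 (erythroid), -0.28 (chemokines) and -0.38 (type I interferon-stimulated genes), against a median of 0.352 over all genes.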

How the results depend on the processing

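The alternatives with a block in wild-type spleens alone, a GC trend removed, the haemoglobin share alone given back, the pancreas score, the Y-linked score and autosomal genes only were chosen after seeing the data, and the others before. In spleen, counts that moved by more than 1.5 times were as follows. A 2-fold minimum gave 623 genes for infection in wild type and 767 for genotype in infected spleen, and a mean of at least 5 RPKM gave 393 for the difference between responses. Fitting only the 2 groups compared gave 944 for infection in wild type and 2 for genotype in uninfected spleen. For infection in libraries labelled knockout, the count was 23 with the GC trend removed and 8 with the pancreas score. Leaving out each library in turn gave 1223 (without wild-type uninfected replicate 3) to 2126 for infection in wild type, 1 to 24 for infection in libraries labelled knockout, 2 to 25 (without wild-type uninfected replicate 1) for genotype in uninfected spleen, 1597 (without wild-type infected replicate 3) to 4266 for genotype in infected spleen and 399 to 869 for the difference.

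In myeloid cells, infection in wild type gave 20 genes with a pseudocount of 0.1, 25 with no filter, 20 with quantile normalization, 61 without haemoglobin genes and rescaled to the same RPKM total, and 12 with only the 2 groups compared. Infection in libraries labelled knockout gave 0 with a pseudocount of 0.1, a mean of at least 5 RPKM, median-ratio scaling, the replicate block and the Y-linked score (limma; 426 at an unadjusted p below 0.05 in the fit reported), 1 with a constant variance prior, 2 with no filter and 3 with quantile normalization. Genotype in infected cells gave 4477 with quantile normalization, and the difference between responses gave 1 without haemoglobin genes and rescaled. With the haemoglobin share alone given back, infection in wild type gave 39. Leaving out each library gave 14 to 41 for infection in wild type and 0 to 10 in libraries labelled knockout. Il27ra turned direction for infection in libraries labelled knockout: from 0.093 to -0.061 with median-ratio scaling, -0.105 with quantiles, -0.216 with the GC trend removed, -0.148 with the Y-linked score, and between -0.062 (without infected replicate 1 labelled knockout) and 0.248 when 1 library was left out. For genotype in uninfected cells it turned from -0.37 to 0.11 without haemoglobin genes and rescaled, and was -0.289 with the share alone given back.

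The replicate block over all groups gave 1717, 14, 5, 3252 and 554 genes in spleen and 33, 0, 4509, 6630 and 0 in myeloid cells, in the order of the comparisons. Over all group pairs same-numbered spleens did not deviate together (median correlation -0.029), and the block is given for them only here. Among named spleen genes of infection in libraries labelled knockout, Stfa2 passed with it (adjusted p = 0.0438). The block in wild-type spleens alone gave 2453 genes, of which 1844 were among the 1858; of the lists called by camera it ended 1, the antimicrobial effectors (adjusted p = 0.057), and of the named genes none. With an estimated correlation it ended 4 list calls and brought 1, the unfolded protein response (adjusted p = 0.0476). Over the named genes and all alternatives, 7543 spleen values kept their direction and their side of the threshold, 193 no longer passed and 18 newly passed. In myeloid cells the numbers were 1854, 236 and 0, with 6 that turned. Over lists, 500 did so and 120 no longer passed in spleen, and 265 and 161 in myeloid cells. The sex covariate was not run, because Xist is in neither table. A fit of only 2 groups could not be made for the differences between responses or for groups with 1 library.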

Other observations

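The genes of this part and the test with the Y-linked score were chosen only after the result was seen. Of the transcripts of the IL-27 subunits themselves, Il27 was low, at 0.62 RPKM in uninfected and 0.2 RPKM in infected wild-type spleen. Ebi3 stood at 5.33 and 6.45 RPKM, and neither change passed in limma (adjusted p = 0.542 and 0.71). Ifitm6 went from 75.1 to 228.7 RPKM in wild-type spleen and from 71.1 to 222.9 RPKM in spleens labelled knockout, while Ms4a6d went from 4.6 to 129.4 and from 4.03 to 11.9 RPKM. The difference between the responses was 0.12 for Ifitm6 (SE 0.299, adjusted p = 0.863) and -3.19 for Ms4a6d (SE 0.223), with 3 libraries per group.

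The Y-linked mean differed with infection among the myeloid libraries labelled knockout, 0.0093 uninfected against 3.37 and 2.89 infected, so sex and infection separate the same libraries there. With the Y-linked score as covariate the change was 3.59 for Ifitm6 and 2.19 for S100a9, against 3.45 and 2.46 without it. The loss of these calls with the score says nothing about sex, since other alternatives ended them too.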
